A study of Mus musculus with 4 samples.

How the data were processed

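Bulk RNA sequencing was made from 4 semimembranosus muscles (a hamstring muscle of the thigh) of C57BL/6 mice aged 8 weeks, in which the left external iliac vein had been narrowed by tying it over a 30-gauge needle. The IVS group (iliac vein stenosis, 2 libraries) received saline by gavage each day and the IVS_diosmin group (2 libraries) received diosmin, a plant flavonoid used as a vein-active drug, at 40 mg per kg per day. Per the labels' protocols, RNA was extracted with Trizol, mRNA was selected with poly-T beads, and the libraries were made with a NEBNext Ultra RNA kit, which is not described there as keeping the strand.

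The deposited values were raw counts of reads per gene, 1 file per library, in the layout that HTSeq writes. HISAT2 2.1.0, HTSeq and the mouse genome mm10 are named in the submitters' processing notes. The HTSeq version, the annotation release, the strand setting and the filters were not given in the sources used here. The files held 55401 genes by versioned Ensembl identifier. Symbols, positions, lengths and GC content came from GENCODE M21 on the same build, where 55141 identifiers matched without their version. Where genes shared a symbol, the gene with the higher mean count carried it.

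Gene counts summed to 15324354 and 13056650 in IVS replicates 1 and 2, and to 13897740 and 14539304 in IVS_diosmin replicates 1 and 2. These were 27.5%, 27.6%, 24.9% and 26.3% of the reads each file accounted for. The 5 summary lines of HTSeq name no gene and stayed out of library sizes and tests. In the same order of libraries, 29.7%, 28.6%, 25.9% and 26.8% of the reads lay in no annotated feature, 37.7%, 38.8%, 45.6% and 43.6% aligned to more than 1 place, and 2.75%, 2.89%, 1.50% and 1.42% did not align. Reads shared by near-identical genes fell in the line for more than 1 place, so members of such families (the alpha globins, the myosin heavy chains, the actins, Hspa1a and Hspa1b, and mitochondrially encoded genes with nuclear copies) have uncertain levels. Genes whose exons lie opposite the exons of another gene on the other strand have uncertain counts too, because reads of a gene and its opposite partner cannot be told apart without strand.

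Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 13533 genes. Library sizes were scaled by TMM, and a quasi-likelihood model with robust estimation tested IVS_diosmin minus IVS, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values below are from this edgeR test unless another tool is named. The biological coefficient of variation was 0.235. Levels are TMM-normalised CPM (counts scaled to the same library size). The standard error of a log2 fold change was its size divided by the square root of the F statistic.

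The labels do not say that the replicates came from separate animals (the series text speaks of different muscles), so p-values measure only the spread between these samples, which may be technical. With 2 libraries against 2, an exact permutation test of 1 gene cannot go below p = 0.333, which is why a model across genes was used. The chi-square over its degrees of freedom between replicates was 31.3 in IVS and 21.5 in IVS_diosmin, so no library was a repeat of another within sampling noise. Ratios and intervals for genes with 3 counts or fewer in a group cover counting error only; the intervals are 95% exact conditional binomial (Clopper-Pearson) intervals, and reads of PCR-amplified libraries are not independent molecules, as for every other interval drawn from counts.

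Before the data were examined, 34 gene lists were fixed: fast fibre contractile, slow fibre contractile, muscle atrophy and denervation, satellite cell and regeneration, extracellular matrix and fibrosis, fibro-adipogenic progenitor, endothelial cell, smooth muscle and pericyte, hypoxia and angiogenesis, macrophage, neutrophil, lymphocyte, inflammatory cytokine and adhesion, interferon response, antioxidant and NRF2, nuclear oxidative phosphorylation, mitochondrially encoded, mitochondrial biogenesis and dynamics, fatty acid oxidation, glycolysis and glycogen, adipocyte, circadian clock, immediate early, heat shock and unfolded protein, glucocorticoid response, aryl hydrocarbon receptor target, cell cycle, apoptosis and p53, erythrocyte, Schwann cell and nerve, neuromuscular junction, tendon, ribosomal protein, and sex-linked. The 32 lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. With 2 libraries per group, camera with an estimated correlation has little power, so a miss there does not decide whether a list shifted. Where members of a list vary together more than the preset allows, the p-values of the preset test can be too small.

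The genes named were set by a rule fixed at the same time. Among genes with an adjusted p under 0.05, a mean CPM of at least 1 and both diosmin libraries on the same side of both IVS libraries, it took the 12 with the largest rise and the 12 with the largest fall, passing over predicted genes and pseudogenes. It added up to 4 members from each list described, in order of p, and the 10 genes of highest mean CPM. Other genes named were chosen after the data were seen, among them Tpm3, Casq2, Myl2 and Kdr of the fixed lists.

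Alternatives fixed beforehand were DESeq2's size factors in edgeR, upper-quartile factors, library sizes without the 10 most abundant and the mitochondrially encoded genes, no filter on low counts, a stricter filter (a CPM of at least 1 in every library of a group), DESeq2 1.42.0, limma-voom, edgeR without robust estimation, the replicate number as a block, and leaving out each library in turn. A correction for transcript length and GC content (loess offsets with a span of 0.5) and a fit without genes that an opposite-strand partner could fill (at least 20% of their mean count) were chosen after seeing the data. So were lists of genes of sterol biosynthesis, caveolae, translocation and folding in the endoplasmic reticulum, fibre type regulation and heart muscle, adjusted among themselves and kept out of the 34. The calculations were tested on simulated data for IVS_diosmin against IVS, with counts drawn for the 13533 genes. Of 100 genes changed by 1 on the log2 scale 28% were recovered, of 100 changed by 2 76%, and 4 of 108 calls were false. Each simulated gene had the spread of the trend at its level and varied independently of the others. The rates may therefore be better than those in the real libraries. Reads were not aligned again, and the genes behind reads aligned to more than 1 place were not analysed here.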

Results

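Poly(A) RNA was sequenced from the semimembranosus muscles of mice with a narrowed left external iliac vein, of which 2 libraries came from mice given saline (IVS) and 2 from mice given diosmin at 40 mg per kg per day (IVS_diosmin). Gene counts ran from 13056650 to 15324354 per library, and 13533 genes had enough counts to be tested. The comparison of the groups asks how gene expression in this thigh muscle differs when mice with the stenosis receive diosmin. No library came from a mouse without stenosis, so the levels have no unoperated reference.

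With diosmin, 10 of 12 slow muscle fibre genes rose, and 5 of 21 interferon response genes did. Of endothelial genes 8 of 18 fell, of heat shock and unfolded protein genes 7 of 21, and of immediate early genes 5 of 19. These 5 lists were shifted as groups by camera, but no such call held with an estimated correlation (adjusted p = 0.335 for the slow fibre and endothelial lists, 0.684 for the interferon and heat shock lists and 0.457 for immediate early genes). In all, 400 genes differed between the groups, 159 higher and 241 lower with diosmin (edgeR quasi-likelihood test, adjusted p under 0.05), and 318 of them by at least 1 on the log2 scale. The count was 98 without IVS replicate 2, 38 without IVS_diosmin replicate 1 and 266 without IVS_diosmin replicate 2, with a lone library assumed to vary like the other group. The balance of falls over rises turned without a diosmin library, to 27 higher and 11 lower without replicate 1 and 140 higher and 126 lower without replicate 2. Of the 400 genes, 235, 81, 32 and 180 passed again without IVS replicate 1, IVS replicate 2, IVS_diosmin replicate 1 and IVS_diosmin replicate 2, and 27 passed every time (18 higher, 9 lower).

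All 12 members of the slow fibre list had higher values with diosmin, and 10 of them rose (12 when adjusted over the list alone), in the libraries where the rRNA share and Rn7sk, described below as quality signs, were lower. Myh7, the slow type I myosin heavy chain (mm10 chromosome 14, 54970684 to 54994626), went from 1.72 and 2.19 CPM in the IVS libraries to 858 ± 567 CPM with diosmin (SD, n = 2), a log2 fold change of 8.79 ± 0.67 (SE, adjusted p = 0.00427). The slow troponins followed, with log2 fold changes of 7.23 for Tnni1, 6.62 for Tnnc1 and 5.74 for Tnnt1. Myl3, the slow ventricular myosin light chain, rose by 5.49, Myoz2, a Z-disc protein of slow fibres, by 3.83, Atp2a2, the slow calcium pump of the sarcoplasmic reticulum, by 3.40, and Casq2, the slow calsequestrin, by 2.03. Myh7b, an ancient slow-type myosin, had the smallest standard error of the list, and went from 6.50 ± 1.27 to 84.6 ± 8.4 CPM (log2 3.71 ± 0.24, adjusted p = 2.45e-05). Tpm3, the slow tropomyosin, rose by 2.48. Myl2, the slow regulatory light chain, did not pass (log2 5.42 ± 0.81, adjusted p = 0.0599). It was at 14.9 and 7.07 CPM in IVS replicates 1 and 2 and at 716 and 231 CPM in IVS_diosmin replicates 1 and 2. Most of these genes were higher in diosmin replicate 1 than in replicate 2, with Myh7 at 1259 and 457 CPM and Tnnt1 at 551 and 274 CPM. Camera placed the list above all other genes (adjusted p = 4.92e-63), and the adjusted p = 0.335 with an estimated correlation. Without IVS replicate 1, Tnnc1 missed the threshold (log2 6.16, adjusted p = 0.0508). Without IVS replicate 2, Myoz2 (3.42, adjusted p = 0.0651) and Casq2 (1.60, adjusted p = 0.150) missed it, and Casq2 did so without IVS_diosmin replicate 1 (1.48, adjusted p = 0.275).

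Fast fibre genes moved both ways. Of 16 members, 1 rose and 2 fell (3 and 5 when adjusted over the list alone), and the list was not shifted (adjusted p = 0.658, with a median log2 fold change of -0.12 and a mean of 0.04). Myh1, the fast type IIx myosin, rose from 566 ± 134 to 1278 ± 304 CPM (log2 1.17 ± 0.24, adjusted p = 0.0261). Casq1, the fast calsequestrin, fell by 0.92 on the log2 scale (adjusted p = 0.0353), and Tnnc2, fast troponin C, fell by 0.93 (adjusted p = 0.0396). Without IVS replicate 2 and without IVS_diosmin replicate 1, the adjusted p of Myh1 was 0.239 and 0.260, that of Casq1 0.228 and 0.221, and that of Tnnc2 0.221 and 0.305. Without IVS_diosmin replicate 2, Casq1 (0.197) and Tnnc2 (0.219) missed the threshold as well. Tnnc2 lies opposite Ube2c, whose own count was 0.861 to 0.984 times that of Tnnc2 in the 4 libraries, so both levels are uncertain. Tnni2, fast troponin I, had 13930 CPM in IVS and 8448 CPM with diosmin (adjusted p = 0.0811). The most abundant myosin, the fast type IIb Myh4, was at 23720 ± 1020 and 20090 ± 363 CPM (log2 -0.24 ± 0.20, adjusted p = 0.621). Myh2, the type IIa myosin chosen after its values were seen, was at 89.7 ± 60.8 and 556 ± 331 CPM and did not pass (log2 2.63 ± 0.74, adjusted p = 0.200).

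**Figure D1:**
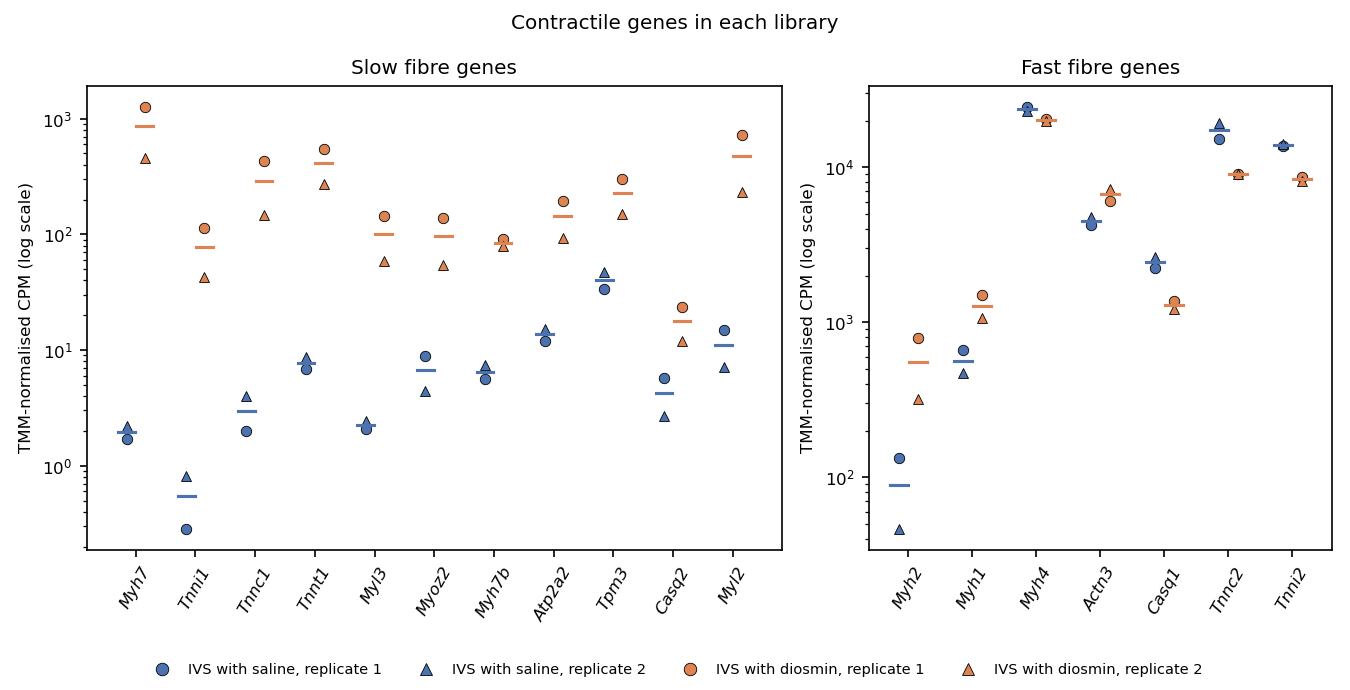
TMM-normalised CPM on a log scale of slow fibre genes (left) and fast fibre genes (right) in each of the 4 libraries, with IVS in blue and IVS_diosmin in orange, replicate 1 as circles, replicate 2 as triangles and bars at the group means. Myh7 lies at 1.72 and 2.19 CPM in the IVS libraries and at 1259 and 457 CPM in the diosmin libraries, while Myh4 stays between 19828 and 24440 CPM in all 4.

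Endothelial genes were lower with diosmin. Of 18 members, 17 had lower values, 8 fell (14 when adjusted over the list alone) and none rose, with a median log2 fold change of -0.91. Cdh5, the cadherin of endothelial junctions, went from 108 ± 4.7 to 42.5 ± 3.5 CPM (log2 -1.34 ± 0.20, adjusted p = 0.00491). Aqp1, a water channel of capillary endothelium and red cells, fell by 1.93, Erg, an endothelial transcription factor, by 1.28, and Esam, a junction adhesion molecule, by 1.15 on the log2 scale. Camera gave an adjusted p = 1.46e-13, and the adjusted p = 0.335 with an estimated correlation. Without IVS_diosmin replicate 1, Cdh5 (log2 -1.42, adjusted p = 0.0841), Aqp1 (-1.60, 0.108), Erg (-1.21, 0.174) and Esam (-1.21, 0.124) missed the threshold. Without IVS replicate 2, Erg (-1.23, 0.134) and Esam (-1.05, 0.106) missed it. Among the largest falls were Cav2, a caveola protein, from 45.0 ± 3.6 to 9.49 ± 1.31 CPM (log2 -2.24 ± 0.22, adjusted p = 0.000704), Apold1, an endothelial early response gene (log2 -2.41), and Nos2, the inducible nitric oxide synthase (log2 -2.26). Of these 3, Cav2 passed without each library in turn, Apold1 missed the threshold without IVS_diosmin replicate 1 (0.102), and Nos2 missed it without any 1 library (0.0762 to 0.185). In the same diosmin libraries the share of gene counts on the rRNA gene described below was lower, and smooth muscle and pericyte genes were not shifted (adjusted p = 0.264). In that list 1 of 13 members rose (1 when adjusted over the list alone), Synpo2 (log2 1.05), an actin-bundling protein that skeletal muscle fibres also express, and it missed the threshold without any 1 library (0.0575 to 0.176).

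Interferon response genes were higher with diosmin, most of all in replicate 1, and the same quality signs (rRNA share and Rn7sk) were lower in these libraries. Of 21 members, 19 had higher values and 5 rose (13 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 1.16, or 0.51 without IVS_diosmin replicate 1. Irf7, the master regulator of type I interferon genes, went from 7.65 ± 1.93 to 51.7 ± 18.9 CPM (log2 2.76 ± 0.30, adjusted p = 0.00148), at 65.1 CPM in diosmin replicate 1 and 38.4 CPM in replicate 2. Oasl2, an oligoadenylate synthetase-like gene, rose by 3.00, Gbp3, an interferon-induced GTPase, by 2.32, and Tap1, the peptide transporter of antigen presentation, by 1.38. Without IVS_diosmin replicate 1 the adjusted p was 0.115 for Gbp3, 0.0719 for Oasl2 and 0.272 for Tap1. Oasl2 and Tap1 also missed the threshold without IVS replicate 1 (0.0718 and 0.10) and without IVS replicate 2 (0.116 and 0.0856). Zbp1, a sensor of nucleic acids, had 2 counts over the IVS libraries and 94 over the diosmin libraries, a ratio of 51.1 (95% interval 13.8 to 428), and missed the threshold without IVS replicate 2 (0.0803) and without IVS_diosmin replicate 1 (0.263). Camera gave the list an adjusted p = 8.43e-11, and the adjusted p = 0.684 with an estimated correlation. Inflammatory cytokine and adhesion genes were not shifted (adjusted p = 0.264), with no member of 11 past the threshold (2 lower when adjusted over the list alone). Cxcl1, a neutrophil chemokine, had 11 and 10 counts in IVS and 0 in both diosmin libraries, and missed the threshold (adjusted p = 0.0998).

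Chaperones and early response genes were lower, in the same libraries in which Rn7sk and the share of counts on an rRNA gene, described below as quality signs, were lower. In the heat shock and unfolded protein list 7 of 21 members fell (9 when adjusted over the list alone) and none rose. Hspa5, the chaperone of the endoplasmic reticulum, went from 96.2 ± 23.6 to 34.6 ± 0.3 CPM (log2 -1.47 ± 0.22, adjusted p = 0.00506). Hsp90aa1 and Hspb1, cytosolic heat shock proteins, fell by 1.56 and by 1.39, and Dnajb1, a co-chaperone of the 70-kDa heat shock proteins, fell by 2.18 on the log2 scale. The list had a camera adjusted p = 1.31e-08, and the adjusted p = 0.684 with an estimated correlation. Its median log2 fold change was -0.84, and -0.43 without IVS replicate 2. Of the 19 immediate early genes 5 fell, also when adjusted over the list alone (5), and 18 had lower values (camera adjusted p = 1.86e-07, and adjusted p = 0.457 with an estimated correlation). Their median was -0.81, and -1.33 without IVS_diosmin replicate 2. Dusp1, a phosphatase of MAP kinases, fell by 1.33 (adjusted p = 0.00776), Zfp36, an mRNA-destabilising protein, by 1.77, and Ier2 and Junb, early transcription regulators, by 1.63 and by 1.82. The calls of Hspa5, Hsp90aa1, Hspb1, Dnajb1, Zfp36 and Ier2 were lost without IVS replicate 2 and without IVS_diosmin replicate 1, with adjusted p between 0.0603 and 0.207. The call of Dusp1 was lost without IVS_diosmin replicate 1 (0.137), that of Zfp36 also without IVS_diosmin replicate 2 (0.190), and that of Junb without every library but IVS replicate 2 (0.133, 0.265 and 0.228).

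Energy metabolism genes split by class, in the same libraries in which the rRNA share and Rn7sk, the quality signs described below, were lower with diosmin. Nuclear genes of oxidative phosphorylation were lower as a list, with 34 of 40 members at lower values and a median log2 fold change of -0.40, but 3 fell singly (9 when adjusted over the list alone). These were Ndufa4 (log2 -0.92), Ndufb3 (log2 -0.93) and Cox5a (log2 -0.83), subunits of respiratory complexes, followed by Ndufa1, which did not pass (log2 -0.82, adjusted p = 0.0532), and each of the 3 missed the threshold in every fit that left out 1 library (adjusted p from 0.0747 to 0.299). Camera gave an adjusted p = 2.28e-06, and the adjusted p = 0.335 with an estimated correlation. The 13 mitochondrially encoded genes had a median of 0.40, none past the threshold in either count (0 when adjusted over the list alone, 1 with lower values), with a camera adjusted p = 0.0197, and adjusted p = 0.877 with an estimated correlation. That call was lost without IVS replicate 1 (median 0.24, adjusted p = 0.354) and without IVS_diosmin replicate 1 (median 0.12, adjusted p = 0.610). Fatty acid oxidation genes were higher as a list (adjusted p = 0.0261, and adjusted p = 0.684 with an estimated correlation), with 3 of 26 higher and 1 lower (5 and 1 when adjusted over the list alone). Acsl1, Acadm and Acadl, enzymes that activate and oxidise fatty acids, rose by 1.01, 0.98 and 0.86, and Cd36, the fatty acid carrier that endothelium and muscle share, fell by 1.39 on the log2 scale. The list missed the threshold without IVS replicate 1 (0.108) and without IVS_diosmin replicate 1 (0.272). Without IVS_diosmin replicate 1, Acsl1, Acadm, Acadl and Cd36 missed it too (0.0814 to 0.243). Of 20 glycolysis and glycogen genes 3 rose (5 higher and 1 lower when adjusted over the list alone), with a camera adjusted p = 0.00115, adjusted p = 0.684 with an estimated correlation, and 0.138 without IVS_diosmin replicate 2. They were Fbp2, the muscle fructose bisphosphatase (log2 1.43), Pgk1, a glycolytic kinase (log2 0.92), and Gys1, glycogen synthase (log2 0.82), while Pgam2, the muscle phosphoglycerate mutase, leaned the other way without passing (log2 -0.66, adjusted p = 0.120). Pgk1 and Gys1 missed the threshold without any 1 library (0.128 to 0.289), and Fbp2 without IVS replicate 2 (0.186) and without IVS_diosmin replicate 2 (0.125). Mitochondrial biogenesis and dynamics genes were higher as a list (adjusted p = 0.0148, adjusted p = 0.684 with an estimated correlation), with 1 of 21 past the threshold (4 when adjusted over the list alone), Mfn2, which fuses mitochondria (log2 0.82) and missed it without any 1 library (0.131 to 0.318). The list missed the threshold without IVS replicate 2 (0.0850) and without IVS_diosmin replicate 2 (0.0673).

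Another 5 lists were shifted with at most 1 member past the threshold, again with the rRNA share and Rn7sk lower in the diosmin libraries. Adipocyte genes were lower (adjusted p = 0.0123, and 0.684 with an estimated correlation), with 1 of 10 members lower (1 higher and 4 lower when adjusted over the list alone), and their call was lost without IVS_diosmin replicate 1 (0.211) and without IVS replicate 2, where the camera direction turned (0.725) and the median went from -1.02 to -0.14. Fabp4, a fatty acid carrier of adipocytes and endothelium, went from 457 to 196 CPM (log2 -1.22 ± 0.22, adjusted p = 0.0121), and missed the threshold without any library but IVS replicate 1 (0.0684 to 0.124), while Car3, the carbonic anhydrase of slow muscle and fat, had a log2 fold change of 2.14 (adjusted p = 0.0506) and Pparg, the regulator of fat cell formation, of -1.85 (adjusted p = 0.0599). Glucocorticoid response genes were lower with no member past the threshold in either count (0 of 17, camera adjusted p = 0.00726, adjusted p = 0.684 with an estimated correlation, 0.211 without IVS replicate 2); Glul, glutamine synthetase, had a log2 fold change of -0.77 (adjusted p = 0.0765). Neuromuscular junction genes were lower (adjusted p = 0.0338, adjusted p = 0.684 with an estimated correlation), with 0 of 14 past the threshold (1 higher and 7 lower when adjusted over the list alone), and the member of smallest p leaned against the list: Colq, the collagen tail of acetylcholinesterase, had a log2 fold change of 1.00 (adjusted p = 0.0760) and Chrnb1, an acetylcholine receptor subunit, of -0.78 (adjusted p = 0.0897). That call was lost without IVS replicate 2 (0.188) and without IVS_diosmin replicate 1 (0.114). Erythrocyte genes were higher (adjusted p = 0.00445, adjusted p = 0.684 with an estimated correlation), with 0 of 5 past the threshold (1 when adjusted over the list alone) and Hba-a1, an alpha globin, at 3.71 and 11.6 CPM. The levels of Hba-a1 and Hba-a2 are uncertain, as near-identical genes share reads aligned to more than 1 place. Alas2 of the list, at 0.196 CPM in IVS and 1.05 CPM with diosmin, could be filled by its opposite partner Apex2. Ribosomal protein genes were higher (adjusted p = 0.0392, adjusted p = 0.935 with an estimated correlation) with 0 of 38 past the threshold, also when adjusted over the list alone (0), and the member of smallest p, Rpl3, leaned the other way (log2 -0.83, adjusted p = 0.0924). The erythrocyte and ribosomal calls were lost without IVS replicate 1 (0.233 and 0.580) and without IVS_diosmin replicate 2 (0.138 and 0.776). No call of any of the 15 lists held with an estimated correlation. That test rests on 2 libraries per group and could hardly pass. Even the slow fibre list, with all 12 members higher, had p = 0.0314 before adjustment (camera with an estimated correlation). Low power is not the only difference between the tests. The estimated correlation between members was 0.877 in the slow fibre, 0.811 in the interferon and 0.721 in the ribosomal list. The preset was 0.01, and the endothelial and nuclear oxidative phosphorylation lists had estimates of 0.0769 and 0.00353. Where members vary together, the preset p-values can be far too small, and the estimates rest on few libraries.

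**Figure D2:**
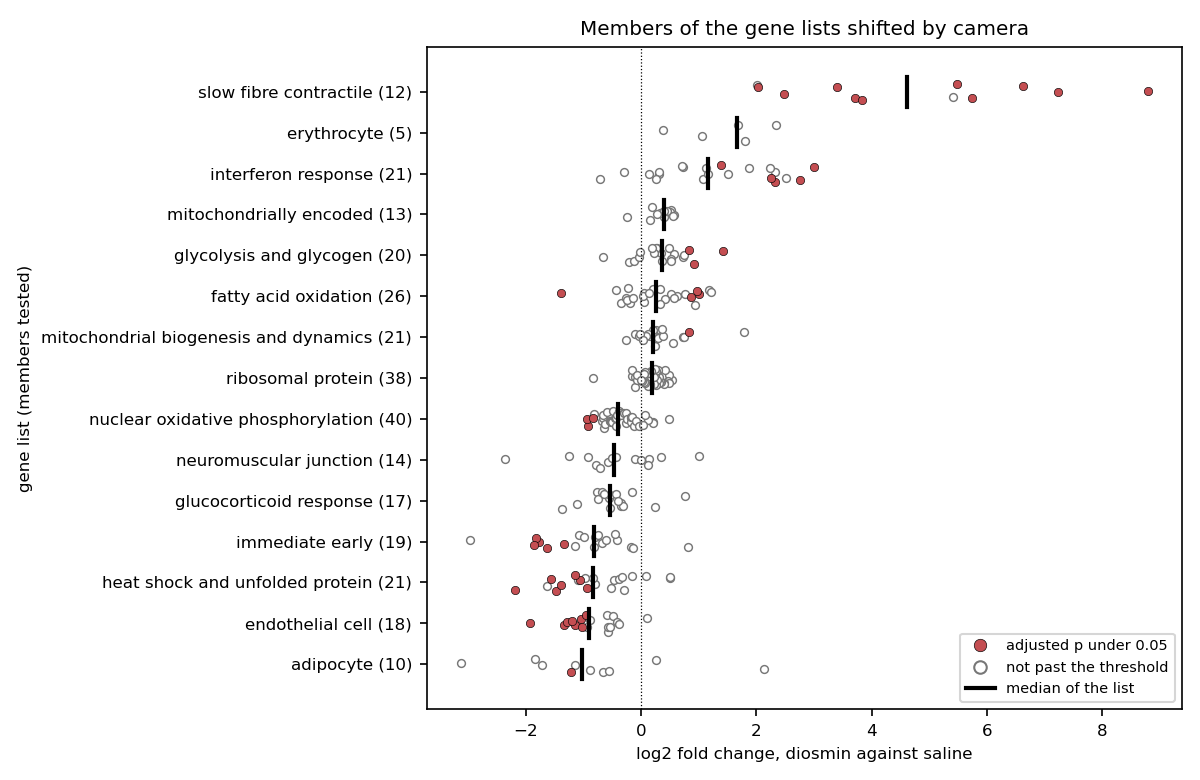
Log2 fold changes (diosmin against saline, horizontal axis) of the tested members of the 15 shifted gene lists (vertical axis, with the number of members), each point 1 gene, filled where its adjusted p was under 0.05, and black bars at the list medians. The slow fibre list has a median of 4.62 and the interferon list of 1.16, while the endothelial list has a median of -0.91 and the immediate early list of -0.81.

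The other lists were not shifted. In the extracellular matrix and fibrosis list (adjusted p = 0.784) 3 of 27 members fell (4 when adjusted over the list alone), Serpinh1, the collagen chaperone (log2 -1.37), Sparc (log2 -1.06) and the basement membrane collagen Col4a2 (log2 -1.03), although its median was 0.11, its mean 0.10 and the camera direction lower. That median turned with the library left out. It was -0.10 and 0.54 without IVS replicates 1 and 2, and -0.24 and 0.42 without IVS_diosmin replicates 1 and 2. Hypoxia and angiogenesis genes went both ways (adjusted p = 0.689), with 3 of 27 higher and 3 lower (5 and 5 when adjusted over the list alone). The kinase Pdk1 (log2 1.06), the oxygen sensor Egln1 (log2 0.99) and Pgk1 rose, and the endothelial Epas1 (log2 -0.95), Flt1 (log2 -0.96) and Kdr fell. Apoptosis and p53 genes (adjusted p = 0.689) held 1 of 18 higher and 1 lower in both counts (1 and 1 when adjusted over the list alone), Ccng1, a p53 target (log2 1.41), and Bcl2l1, which opposes apoptosis (log2 -1.95). Muscle atrophy and denervation genes (adjusted p = 0.551) had 1 of 26 higher and 1 lower (2 and 2 when adjusted over the list alone), Eif4ebp1, a repressor of translation (log2 1.20), and Ctsl, a lysosomal protease (log2 -1.44). Fibro-adipogenic progenitor genes (adjusted p = 0.658) had 1 of 14 higher and 1 lower (2 and 1 when adjusted over the list alone), Opcml, at 0.14 and 1.89 CPM, and Cd34, which endothelium also carries (log2 -1.05). Satellite cell and regeneration genes (adjusted p = 0.689) had 1 of 16 higher (1 when adjusted over the list alone), Actc1, the cardiac actin of developing muscle (log2 1.04). In the circadian clock list (adjusted p = 0.949) 1 of 18 fell (1 when adjusted over the list alone), the repressor Nr1d1 (log2 -0.94). Every gene named in this paragraph missed the threshold without IVS_diosmin replicate 1 (0.0700 to 0.260). The lists depended on single libraries too, as muscle atrophy genes were lower without IVS replicate 1 (adjusted p = 0.00246), fibro-adipogenic genes higher without IVS replicate 2 (0.0136) and extracellular matrix genes lower without IVS_diosmin replicate 1 (0.0313).

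No member passed the threshold in the remaining lists of other cells and responses. These were macrophage (0 of 15, adjusted p = 0.689), Schwann cell and nerve (0 of 14, 0.487), antioxidant and NRF2 (0 of 24, 0.949), aryl hydrocarbon receptor target (0 of 4, 0.689), cell cycle (0 of 13, 0.0888), tendon (0 of 4, 0.689) and sex-linked genes (0 of 4, 0.964). Macrophage and Schwann cell genes turned with the IVS library left out, lower without replicate 1 (medians of -0.68 and -1.35, adjusted p = 0.00546 and 4.15e-08) and higher without replicate 2 (medians of 0.60 and 1.01, adjusted p = 0.0170 and 0.000785). Cell cycle genes were lower under the stricter filter (adjusted p = 0.0173). When adjusted over the list alone, 2 cell cycle genes and 1 tendon gene were lower and the other 5 lists had 0. The tendon list had a median of 0.08 and a mean of -0.23, and the sex-linked list a median of 0.04 and a mean of -0.04. The members of smallest p were Lgals3 (log2 -1.12 ± 0.50) for macrophages, Pllp (log2 -2.49 ± 1.04) for Schwann cells, Gsta4 (log2 -1.20 ± 0.38) for antioxidant genes, Nqo1 (log2 0.61 ± 0.30) for aryl hydrocarbon receptor targets, Fmod (log2 -1.84 ± 0.55) for tendon and Hmgb2 (log2 -1.73 ± 0.45) for the cell cycle. Second among cell cycle genes, Ube2c stood at 15360 CPM in IVS and 8736 CPM with diosmin, but it lies opposite Tnnc2 and its level is uncertain. The lymphocyte and neutrophil lists had only 2 and 1 tested members with all libraries and were not tested as lists there. In fits that kept more members, lymphocyte genes were higher with no filter (adjusted p = 0.0462), without IVS replicate 2 (0.00101) and without IVS_diosmin replicates 1 (0.000729) or 2 (0.0167), and not past the threshold without IVS replicate 1 (0.139). Ighm, the immunoglobulin mu heavy chain, rose from 16.7 ± 3.2 to 132 ± 58 CPM (log2 2.99 ± 0.32, adjusted p = 0.00269; 1 of 2 lymphocyte genes, also when adjusted over the list alone). Mmp9 of the neutrophil list had 16 and 18 counts in IVS and 2 and 4 with diosmin (adjusted p = 0.208; lower when adjusted over the list alone).

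Outside the lists, the largest rises included Lgi1, a secreted leucine-rich protein, Cyfip2, a regulator of actin assembly, and mt-Tn, a mitochondrial tRNA. Each had 1 to 3 counts over the IVS libraries, and the ratios of counts were 81.5 (95% interval 14.2 to 3260), 73.9 (12.8 to 2960) and 22.5 (7.34 to 112). Dkk2, a Wnt antagonist, rose by 3.77 (adjusted p = 0.0396) and Cd28, a costimulatory receptor of T cells, by 3.77 (adjusted p = 0.0307), both from under 1 CPM. Among the falls, Dkk3, of the same family as Dkk2, went from 10.3 ± 0.7 to 0.53 ± 0.53 CPM (log2 -4.23 ± 0.54, adjusted p = 0.00292). Cyp2e1, a cytochrome P450, fell by 3.26, Cttnbp2nl by 2.54, Eva1a by 2.52, Spry4, an inhibitor of growth factor signalling, by 2.51, Cyyr1 by 2.36, Lrrc8c, a subunit of volume-regulated anion channels, by 2.32 and Klhl2 by 2.30 on the log2 scale, with adjusted p from 0.00320 to 0.0433. Dkk3 passed without each library in turn, and the other genes of this paragraph all missed the threshold without IVS_diosmin replicate 1 (0.0841 to 0.334).

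A few genes took much of each library. The 10 most abundant genes held 37.3%, 43.1%, 46.2% and 42.9% of gene counts in IVS replicates 1 and 2 and IVS_diosmin replicates 1 and 2. They were mt-Co1, mt-Cytb, mt-Nd1, mt-Nd4, mt-Nd2 and mt-Nd5 of the respiratory chain, Myh4, Ckm (muscle creatine kinase), Acta1 (skeletal actin) and CT010467.1, a gene annotated as rRNA. Mitochondrially encoded genes together held 31.5%, 38.5%, 45.0% and 40.7%. The rRNA gene held 4.14% and 3.80% in IVS and 1.16% and 0.936% with diosmin (log2 -1.81 ± 0.23, adjusted p = 0.00269, or 0.0740 without IVS_diosmin replicate 1), as a sign of RNA that poly(A) selection should remove. Rn7sk, a nuclear RNA without a poly(A) tail chosen after its values were seen, was lower in the same libraries (log2 -1.94 ± 0.30, adjusted p = 0.00630). The other RNAs looked at with it (Rmrp, Rpph1, Rn7s1, Rn7s2, Terc, Rny1 and Rny3) had at most 0.114 CPM in any library and could not be tested.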

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

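The share of reads that aligned to more than 1 place lies outside the gene counts that the comparisons used. It was 45.6% in IVS_diosmin replicate 1 and 43.6% in IVS_diosmin replicate 2, above the 37.7% and 38.8% of the IVS replicates. This signal was singled out because it comes from reads outside the comparison and was higher in both diosmin libraries than in both saline libraries. Classes lower with diosmin were not searched for. Reads not aligned, in no annotated feature and of low alignment quality were each lower in both diosmin libraries. Those of low alignment quality were 0.80% and 0.78% in IVS_diosmin replicates 1 and 2 and 1.10% and 1.05% in IVS replicates 1 and 2. Each group held 2 libraries, where the rule used for a sample far from its group needs 4, and there was 1 contrast, with no second one to compare it with. The genes behind the reads aligned to more than 1 place were not identified, and no explanation was tested.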

How the results depend on the processing

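The count of 400 genes (159 higher, 241 lower) ranged from 293 to 461 under the other scalings, the stricter filter, limma-voom, edgeR without robust estimation and, chosen after seeing the data, the length and GC correction and the fit without genes an opposite-strand partner could fill. It was 919 (394 higher, 525 lower) with no filter on low counts, which tests 22446 genes, and 613 (266 higher) by the DESeq2 Wald test, whose cause was not tested. It was 737 at an adjusted p under 0.1 and 318 with a log2 change of at least 1. Leaving out each replicate in turn gave 38 to 366 genes, 27 to 140 higher and 11 to 257 lower, each with fewer samples; the share higher was 39.8% with all libraries, 29.8% and 37.8% without IVS replicates 1 and 2, and 71.1% and 52.6% without IVS_diosmin replicates 1 and 2, so the direction of the majority turned. A block for the replicate number gave 93 genes (44 higher, 49 lower), and 312 with the length and GC correction. Same-numbered libraries did not deviate together over 9193 genes taken as a whole (correlation of -0.03). This cannot exclude an animal, day or batch shared by number that moved some of the genes, and the labels do not say. The number of shifted lists was 15 with all libraries and ranged from 12 to 16 in 14 other edgeR fits, but the lists themselves changed. The slow fibre, endothelial, interferon, nuclear oxidative phosphorylation, immediate early and heat shock lists passed in all 14. Every other list of the 15 lost its call without at least 1 library. No lists were tested with DESeq2 or limma-voom. The number became 0 with camera's estimated correlation, which has little power here, and 0 with fry, where the lowest adjusted p were 0.335 and 0.116. Of 98 called genes examined singly, 96 to 98 passed again under the other 3 scalings, 90 by DESeq2, 83 by limma-voom, 80 without robust estimation, 38 with the replicate block and 19 to 68 with 1 library left out. Among genes never past the threshold, mt-Nd5 turned to -0.0573 without IVS replicate 1 (0.464 without IVS replicate 2), and Ckm to -0.14 and -0.0667 without IVS replicate 1 and IVS_diosmin replicate 2 (0.252 without IVS replicate 2). Depth limits genes such as Lgi1 and Zbp1, with 1 and 2 counts in IVS.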

Other observations

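The tests in this part were chosen after the result was seen, except that of the other splits; the heart muscle test (whose bound was set before its own value was seen), the length and GC correction, the comparison of each cell type with the endothelial genes and the test of scaling, which took the place of a planned one that moved nothing, are among those chosen afterwards. For sterol, caveola, endoplasmic reticulum and fibre type regulator genes, the bounds that decide each reading were also changed after the p-values were seen, and adjusted p-values over the lists added then took the place of unadjusted ones. Among genes outside the fixed lists, Mvd, an enzyme of the mevalonate pathway, was among the firmest rises, from 7.10 ± 0.96 to 39.8 ± 3.2 CPM (log2 2.48 ± 0.23, adjusted p = 0.000417), and passed without each library in turn. Of 19 tested genes of sterol biosynthesis, Mvd and Fdft1 (log2 0.96, opposite another gene and so uncertain) rose and Hsd17b7 fell (log2 -1.61), and the adjusted p was 0.992 (limma camera). Caveola genes were lower as a list by camera (adjusted p = 1.39e-07, and adjusted p = 0.146 with an estimated correlation), with 6 of 12 lower, among them Cav1 (log2 -1.52), Cavin1 (log2 -1.37) and Cav2. Endothelial genes, whose cells are rich in caveolae, had a median of -0.91 in the same libraries, and Rn7sk and the rRNA share were lower there as well, so this is not shown to be a separate response. The muscle-specific Cav3 (log2 0.41 ± 0.21) and Cavin4 (log2 0.58 ± 0.20) did not pass. Without IVS_diosmin replicate 1, Fdft1, Hsd17b7, Cav1 and Cavin1 missed the threshold (0.108 to 0.274).

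In these libraries with lower Rn7sk and rRNA share, genes for protein entry into the endoplasmic reticulum and folding in it were also lower (camera adjusted p = 2.46e-08, and adjusted p = 0.301 with an estimated correlation). Of 25 tested, 7 fell and none rose, with Rpn1 of the glycosylation complex at log2 -1.49 ± 0.23, the chaperone Hsp90b1 at -1.35 ± 0.21 and the channel subunit Sec61b at -1.30 ± 0.28. Csrp3 and Fhl1, LIM proteins of striated muscle, rose by 2.45 and by 1.78. Csrp3 passed without each library in turn, while Rpn1, Hsp90b1, Sec61b and Fhl1 missed the threshold without IVS_diosmin replicate 1 (0.0905 to 0.221). Regulators of fibre type were not shifted as a list by camera (adjusted p = 0.142). None of 17 tested passed, with Vgll2 nearest (log2 1.04 ± 0.29, adjusted p = 0.0765). Prox1 of the same list had too few counts to be tested. It was at 0.114 and 0 CPM in IVS replicates 1 and 2 and at 3.24 and 0.555 CPM in IVS_diosmin replicates 1 and 2. Under the bound first written, the result of the list counted against a joint change. The bound was replaced after the result was seen, because missing a threshold does not show the absence of a change, and the case is now left open: some members have 95% intervals that reach past 1 on the log2 scale, as Esrrb does (log2 1.41 ± 0.89). Ighm rose to 91.1 and 174 CPM in the diosmin libraries while Igkc, Cd79a and Ms4a1 of the same lymphocyte list had at most 15 counts in any library.

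For the higher slow fibre genes, heart muscle in the samples is argued against, since Myh6, Myl7, Nppa and Tnni3 together reached at most 1.72% of the Myh7 CPM, under the bound of 5%. Scaling moves all genes of a library alike and is argued against too, since the slow fibre median of 4.62 lay above the fast fibre median of -0.12 in the same libraries (permutation test, p = 8e-05; genes are not independent replicates). Slow muscle of one fixed composition, mixed into both diosmin samples, could not be excluded. It would give every slow gene the same ratio of gain between diosmin replicates 1 and 2, which was 2.76 (95% interval 2.68 to 2.84) for Myh7, and 1 of 10 called genes lay below it by more than the factor of 1.3 set as the bound, where at least 2 were needed to exclude the mixture: Myh7b at 1.16 (1.06 to 1.28), with Tnnt1 at 2.04 and Atp2a2 at 2.28 also wholly below the Myh7 interval, by less, and with intervals that leave out the spread between diosmin muscles. A larger share of slow fibres in the part of muscle sampled and a change of fibre type with diosmin remain open and may both hold, since no fibres were counted.

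The lower endothelial genes (median log2 fold change of -0.91) are not accounted for by a fall in every non-muscle cell type alike. Smooth muscle and pericyte genes (median 0.09, permutation test, p = 0.00072 after multiplying by 4) and fibro-adipogenic genes (median 0.12, permutation test, p = 0.00096 likewise) lay above them. With 1 library left out, the fibro-adipogenic median ran from -0.22 to 0.37. Both lists still lay above the endothelial genes without each library in turn, the fibro-adipogenic one by 0.57 to 1.21, though genes are not independent replicates. Macrophage (median -0.50, permutation test, p = 0.387 likewise) and Schwann cell genes (median -0.70, p = 1 likewise) did not differ from them by this test and turned with the IVS library left out, so a joint fall with these stays open. Nor is gene length or GC content the whole cause, since the median was -0.87 after that correction. A smaller share of endothelial cells, lower expression in each of them, and an effect of diosmin on either remain open as hypotheses and were not tested.

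Genes opposite an abundant gene carried high counts, as Ube2c did opposite Tnnc2 (chromosome 2, 592 shared exon bases). A candidate explanation is that reads of the partner were assigned by strand from a kit that does not mark strand. In 29 pairs with at least 50% of a gene's exon bases in the overlap, the median count was 1.79 times that expected from the partner's reads per base. That meets the bound set, a median within a factor of 3, but weakly. Only 9 pairs were themselves within that factor and 5 lay under 0.05, which this explanation leaves unaccounted for. Ube2c was not among these genes, with 592 of its 2600 exon bases in the overlap, while Tnnc2 opposite Ube2c was (4.83 times). The ribosomal protein genes Rpl23a and Rpl35 had 14.8 and 5.93 times the expected count. A gene's own transcripts enter its count too, so the median cannot separate them from reads of the partner. No biological explanation was tested. The fit without such genes, chosen after seeing the data, gave 359 genes.

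For the 400 genes that differed, the 4 libraries allow only 3 splits into groups of 2, too few for a share under 0.05. The real split, 1 of the 3, gave 400 genes and the highest of the others gave 0, where edgeR called none. Each of the other splits put an IVS and a diosmin library together, so a difference between the real groups became spread within groups. No conclusion on chance is drawn from the 0.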
